A study of Homo sapiens with 11 samples.

How the data were processed

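RNA from 3 groups of the human breast cancer line MCF7 was measured on 1-colour Agilent whole-genome expression arrays, 1 array per sample. Per the labels, the groups were MCF7 (4 arrays), MCF7-RON/MSP, which stably expresses the receptor RON and its ligand MSP from retroviruses (4 arrays), and MCF7-RON/MSP-shMBD4, which also carries a short hairpin RNA against MBD4 from a lentivirus (3 arrays). The labels speak of triplicate biological replicates of hybridization for each line, while MCF7 and MCF7-RON/MSP have 4 arrays each. They do not say whether the 4 are distinct biological replicates, nor whether replicates are separate cultures, passages or clones. The labelling protocol in the labels used oligo dT priming, linear amplification with Cy3 and external spike-in RNAs.

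The scanner output was made with Agilent Feature Extraction 10.5.1.1, per the file headers. The deposited scanner files give the intensity of each spot, which the authors left background-subtracted and detrended within each array, with no scaling between arrays, per the file headers. The deposited value table of the series holds log2 values. Each of its columns equalled log2 of the same array's processed intensity within 0.01 for over 99.9% of probes, with no scaling between arrays. Its column medians were 7.41, 7.47, 7.39 and 7.35 in MCF7, 7.53, 7.6, 7.6 and 7.61 in MCF7-RON/MSP, and 8.38, 8.66 and 8.85 in the knockdown arrays. Nothing in its scale or direction stayed unknown.

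Signals were read for 41000 non-control probes in 43376 spots per array. Spots that the software had marked as non-uniform or as population outliers were left out, spots of 1 probe were averaged, and no spot was saturated. The main values were log2 of the processed signal minus each array's 75th percentile. Probes were named through their accession (26222 probes), their symbol (1646) or an older symbol (466) in a RefSeq gene table of another genome build, used for names only. A further 4946 probes kept the name in the files and 7720 had only a probe ID. Each gene was represented by its probe with the highest mean signal. A gene was tested if that probe was well above background on every array of at least 1 group, which left 25931 genes and unnamed probes, 15748 of them with a symbol. Where a named gene was not well above background on any array of a group, the fold is a lower bound, taken against the higher of the probe's own signal and the lowest signal of a probe well above background on each array. These bounds hold for the processed signal and the main scaling. Normexp, whose offset of 50 draws dim signals together, gave smaller changes than the bound for every bounded gene named in the report. List medians and counts at bounds set such genes to this bound, or to 0 where no direction was left.

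All 11 arrays entered 1 limma fit of group means (limma 3.58.1, R 4.3.3) with moderated tests and Benjamini-Hochberg adjustment over the genes tested. The fit estimates 1 spread per gene over all groups. The SE and p-value of a comparison thus also carry the spread of the group that it leaves out. A gene passed at an adjusted p under 0.05, and the counts given first also needed a change of at least 2-fold. The 22 gene lists were tested with camera at a preset correlation between genes of 0.01, with camera at an estimated correlation, and with fry, which asks whether a list's genes move, on balance, one way and compares them with no other gene. Camera sets a list against all other genes, so its direction can differ from the sign of the list's median. The lists covered MAPK feedback and immediate targets, estrogen receptor targets, luminal identity, basal and myoepithelial genes, epithelial junctions, mesenchymal genes, invasion and metastasis, TGF-beta targets, NF-kB and inflammatory genes, interferon response, antigen presentation, cell cycle, DNA methylation and base excision repair, mismatch repair, germline and cancer-testis genes, p53 targets, hypoxia and glycolysis, the unfolded protein and amino acid response, cholesterol synthesis, fibroblast markers, blood and immune cell markers, and housekeeping genes. Tables were made with Python 3.11.15 and pandas 2.3.3 and plots with matplotlib 3.10.9.

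The comparisons, the lists, their tests, the rule for naming genes and the alternatives, except the count of genes that pass under both scalings, were fixed before the data were examined. The rule named MBD4, MST1R and MST1. It then named the 10 largest rises and falls in the comparisons of MCF7-RON/MSP with MCF7 and of the knockdown with MCF7-RON/MSP, and the 5 largest of each in the knockdown against MCF7. These genes had to pass, to be well above background on every array of both groups and to have groups that did not overlap, which chance gives in 2.86% of splits of 4 against 4 arrays and 5.71% of splits of 4 against 3. It further named up to 5 genes per direction with the largest lower bound, up to 4 passing members of each list with the largest change, and the 10 strongest opposite moves each way. Genes were left out for length only from the bottom of these rankings.

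The alternatives were normexp background correction with an offset of 50, quantile normalization, median centring, the series table, no filter or a strict filter, the mean of a gene's probes or every probe on its own, spots marked as outliers kept, an intensity trend with a robust prior, only the groups compared in the fit, the replicate number as a block, the slide as a random block, each array left out in turn, no fold threshold, and MCF7-RON/MSP arrays split so that comparisons shared none. Scaling matters here: against the 75th percentile, quantile normalization moved the median log2 fold change of all genes by -0.09 for MCF7-RON/MSP against MCF7, by -0.18 for the knockdown against MCF7-RON/MSP and by -0.34 for the knockdown against MCF7. Normexp moved these medians by -0.06, -0.24 and -0.41, and median centring by 0, -0.2 and -0.2. The shift differed with signal: for the knockdown against MCF7-RON/MSP the median was 0.41 in the dimmest and -0.33 in the brightest of 5 signal groups, so 1 shift for all genes does not remove it. List medians were therefore also set against 10000 random lists matched on signal, a test planned for the blood and immune cell markers and extended to the other lists after the data were seen.

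Per the file headers, MCF7 lay on 1 slide and MCF7-RON/MSP on another, scanned on the same day with the same scanner. The knockdown arrays lay on a pair of further slides, replicate 1 on one and replicates 2 and 3 on the other, and were scanned on a later day with another scanner and a later protocol version. No block could therefore separate slide from group in the comparison of MCF7-RON/MSP with MCF7, or scan day from the knockdown. Between 73.2% and 88.0% of non-control spots were well above background on an array, and the number of arrays limits the precision. Correlations between arrays of a group ran from 0.987 to 0.997. The steps were tested on simulated data with 200 changed genes among 25931. In the comparison shaped like MCF7-RON/MSP against MCF7, 74% of genes with a true log2 change of 1 and 96% with 2 were recovered, with 3.4% false calls. In the comparison shaped like the knockdown against MCF7-RON/MSP, 80% and 92% were recovered, with 7.5% false calls.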

Results

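Transcript levels were measured in MCF7, a human luminal, estrogen receptor-positive breast cancer line, in MCF7-RON/MSP and in MCF7-RON/MSP-shMBD4. RON, encoded by MST1R, is a receptor tyrosine kinase, and MSP, encoded by MST1, is its ligand. MBD4 is a DNA glycosylase that binds methylated CpG sites and removes thymine and uracil from mismatches with guanine. There were 4, 4 and 3 arrays in these groups. The labels name no group with an empty vector or a control hairpin. Effects of the viral vectors thus cannot be told apart from those of RON/MSP or of MBD4 loss. Spots well above background made up 73.2% to 80.8% of the non-control spots of an array in MCF7, 78.1% to 83.0% in MCF7-RON/MSP and 85.9% to 88.0% in the shMBD4 cells. Over these spots the 75th percentile of the processed signal ran from 2038 to 2254, from 2184 to 2312 and from 2737 to 4049 intensity units. Values below are log2 signals relative to each array's 75th percentile over probes, with spots marked as outliers left out. Fold changes are differences of group means with the standard error (SE) of the limma fit, and p-values are limma's, adjusted over all genes tested.

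The introduced and targeted genes were read first. MBD4 was 1.52 ± 0.02 (SD, n = 4) in MCF7, 1.68 ± 0.06 (SD, n = 4) in MCF7-RON/MSP and -0.81 ± 0.16 (SD, n = 3) in the shMBD4 cells. It was thus 5.61-fold lower in shMBD4 than in MCF7-RON/MSP (log2 -2.49, SE 0.07, adjusted p = 8.86e-09) and 5.03-fold lower than in MCF7 (log2 -2.33, adjusted p = 1.12e-08), with every shMBD4 array below every other array. Between MCF7-RON/MSP and MCF7 the MBD4 difference of 0.16 (SE 0.07) did not pass (adjusted p = 0.0832), although it passed without shMBD4 replicate 3 (adjusted p = 0.0081) or with only those groups in the fit (adjusted p = 0.0112). MST1R rose 25.1-fold in MCF7-RON/MSP over MCF7 (log2 4.65, SE 0.46, adjusted p = 0.000131). In shMBD4 it fell 5.14-fold from MCF7-RON/MSP (log2 -2.36, SE 0.50, adjusted p = 0.00208), and its arrays read -1.13, -1 and 1.40 for replicates 1, 2 and 3, against a mean of 2.12 ± 0.04 (SD, n = 4) in MCF7-RON/MSP and -2.53 ± 0.15 (SD, n = 4) in MCF7. Over the shMBD4 arrays the SD of MST1R was 1.43, so the size of its fall is imprecise. The fit shares this spread, so the SE of the rise over MCF7 carries it too. MST1 rose 1.5-fold in MCF7-RON/MSP (log2 0.59, SE 0.14, adjusted p = 0.00726) and a further 1.32-fold in shMBD4 (log2 0.40, SE 0.15, adjusted p = 0.0387). Leaving out any of 8 arrays ended that last call, with adjusted p = 0.0505 and 0.0516 without MCF7 replicates 2 and 3, 0.076, 0.0694, 0.06 and 0.0699 without MCF7-RON/MSP replicates 1 to 4, and 0.0858 and 0.149 without shMBD4 replicates 2 and 3, and median centring (log2 0.20, adjusted p = 0.29), the replicate number as a block and the slide as a random block ended it too. The probes lie on chromosome 3 of hg19, the build of the later files, at 129150330 to 129150389 for MBD4 (A_23_P92154), 49924693 to 49924752 for MST1R (A_23_P256312) and 49721551 to 49721610 for MST1 (A_24_P148796). The files give no exon and do not say whether the probes for MST1R and MST1 lie within the introduced sequences.

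**Figure D1:**
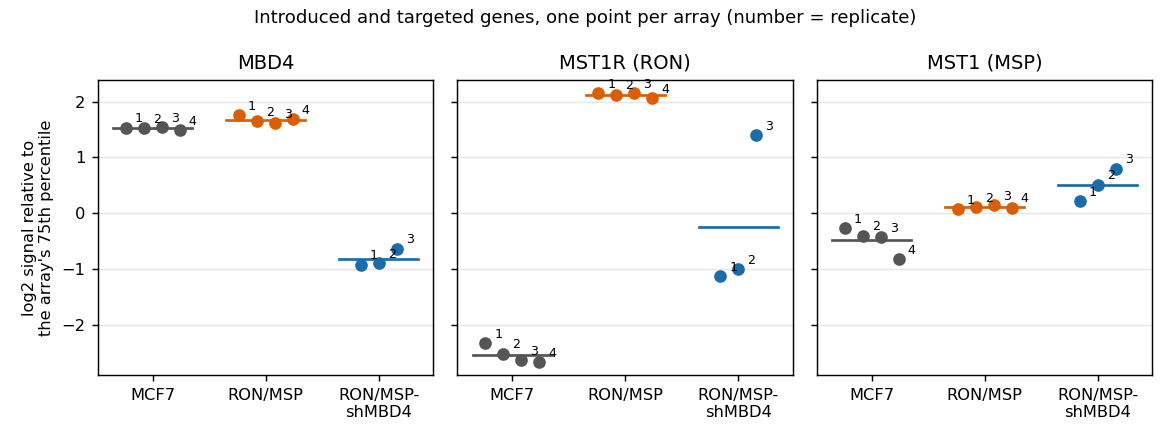
Log2 signal of MBD4, MST1R (RON) and MST1 (MSP) relative to each array's 75th percentile, 1 point per array with its replicate number and a line at the group mean. MBD4 is near -0.81 in the shMBD4 arrays, while MST1R reads -1.13, -1 and 1.40 there against 2.12 on average in MCF7-RON/MSP.

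The comparison of MCF7-RON/MSP with MCF7 asked what RON and MSP change in these cells. Apart from MST1R, the largest rises were in genes with dim signals, such as the hormone subunit gene CGA (5.57-fold) and the homeobox genes HOXB3 (4.65-fold) and HOXB2 (4.32-fold). The HOXB3 value is of its brightest probe (log2 2.22, but 0.92 under normexp), while another probe read 0.04. The falls were larger and began from brighter signals: the sperm protein genes SPANXD and SPANXA1 fell 21.1-fold and 20.8-fold, the neuroendocrine transcription factor ASCL1 17.6-fold and the inflammatory genes S100A8 and LTB 14.3-fold and 8.08-fold. The chemokine receptor gene CXCR4 rose 2.84-fold. The collagenase gene MMP1, above background on 3 of 4 MCF7 arrays, rose 5.6-fold (log2 2.49, but 0.87 under normexp). In total 8704 genes rose and 3538 fell, of which 2420 and 302 changed at least 2-fold. The balance of 2-fold changes turned with the scaling: 476 rose and 626 fell under quantile normalization, and 68 rose and 114 fell under normexp. Of the 2420 rises, 459 were of genes not above background on any array of at least 1 of these groups, and 49 of those reached 2-fold at their lower bound.

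Among the 10 largest rises, CGA encodes the alpha subunit shared by glycoprotein hormones (log2 2.48, SE 0.31, adjusted p = 0.000311). NEURL3, a ubiquitin ligase, rose by 2.31 (adjusted p = 0.00627), and GAGE12F, of a cancer-testis family with near-identical copies that the probe may not tell apart, by 2.22 (adjusted p = 0.00152). HOXB3 rose by 2.22 (adjusted p = 0.000983) on its brightest probe, while another of its probes read 0.04. HOXB2 rose by 2.11 (adjusted p = 0.000151), the nuclear receptor gene NR4A3 by 2.03 (adjusted p = 0.000798), the carboxylesterase gene CES1 by 2.02 (adjusted p = 0.000148) and SHC4, an adaptor of receptor tyrosine kinases, by 1.93 (adjusted p = 0.000714). OLFML1, a secreted protein gene, rose by 2.17 (adjusted p = 0.0232), but MCF7-RON/MSP replicate 2 lay at -0.84 against -4.11 to -3.86 in the other arrays of its group, and the call ended without MCF7 replicate 1 (adjusted p = 0.0555) or replicate 2 (adjusted p = 0.0608) and with the slide as a random block (adjusted p = 0.0765). On no MCF7 array were ADGRL4 and ADGRD1, genes of adhesion receptors, or COL15A1, a basement membrane collagen gene, well above background. Their levels in MCF7-RON/MSP were at least 3.93-fold (adjusted p = 0.000234), 3.23-fold (adjusted p = 0.0125) and 2.85-fold (adjusted p = 0.000187) higher by the processed signal (log2 0.68, 0.31 and 0.34 under normexp), and the ADGRD1 call ended under quantile normalization (adjusted p = 0.0976) and normexp (adjusted p = 0.0672).

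Among the 10 largest falls, SPANXD (log2 -4.40, SE 0.24, adjusted p = 6.02e-06) and SPANXA1 (log2 -4.38, SE 0.21, adjusted p = 3e-06) are near-identical X-linked genes whose probes may read the same transcripts. SLC6A14, an amino acid transporter gene, fell by 4.27 (adjusted p = 0.00182), ASCL1 fell by 4.13 (adjusted p = 0.000267) and CFB, which encodes complement factor B, fell by 3.96 (adjusted p = 5.3e-05). SEMA3D, a secreted guidance factor gene, fell by 3.92 (adjusted p = 0.000672). S100A8 fell by 3.83 (SE 0.11, adjusted p = 1.65e-07) and S100A7 fell by 3.25 (SE 0.09, adjusted p = 1.65e-07), both small calcium-binding proteins of inflamed epithelia. LTB, a cytokine of the tumour necrosis factor family, fell by 3.02 (adjusted p = 7.16e-05) and BRINP3, a gene mainly of neurons, fell by 3 (adjusted p = 0.0106). KLK12, a secreted protease gene, TRPC6, a calcium channel gene, and PHACTR3, an actin regulator gene, were not well above background on any MCF7-RON/MSP array. KLK12 was higher in MCF7 by at least 3.39 on the log2 scale (adjusted p = 4.42e-05), and TRPC6 and PHACTR3 were at least 2.59-fold (adjusted p = 0.000161) and 2.53-fold (adjusted p = 0.00245) higher. These bounds hold for the processed signal, and under normexp the changes were -1.35, -0.36 and -0.34.

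Of the gene lists, epithelial junctions moved down against all other genes, with 7 of 24 members fallen and 1 risen (camera adjusted p = 0.0169, adjusted p = 0.385 with an estimated correlation, 0.0518 with the strict filter). PATJ, a tight junction scaffold, fell by 0.82 (adjusted p = 0.004), with -0.15 to -0.79 on its other probes. TGF-beta targets moved down with 10 of 18 fallen and 4 risen (camera adjusted p = 0.0169, adjusted p = 0.322 with an estimated correlation, 0.0518 with the strict filter). The ligand gene TGFB2 fell by 1.51 (adjusted p = 0.0241) and the differentiation inhibitor ID2 fell by 0.81 (adjusted p = 0.000502), while BAMBI, a decoy receptor for the pathway, rose by 1.22 and LTBP2, a matrix protein gene, by 1.21 on its brightest probe, with 0.49, 0.27 and 0.14 on the others, of which only the first passed. The TGFB2 call ended without MCF7-RON/MSP replicate 1 (adjusted p = 0.0538) or replicate 4 (adjusted p = 0.0521) and with the slide as a random block (adjusted p = 0.0727). In DNA methylation and base excision repair, 7 of 28 fell and 4 rose, or 8 and 1 under quantile normalization (camera adjusted p = 0.0326, adjusted p = 0.322 with an estimated correlation, 0.0501 without MCF7-RON/MSP replicate 4, 0.0764 under normexp, 0.0818 with the strict filter), among them TET2, a methylcytosine dioxygenase (log2 -0.54), and UHRF1, a maintenance methylation factor (log2 -0.52). Blood and immune cell markers rose in 9 of 10 (camera adjusted p = 0.0169, adjusted p = 0.322 with an estimated correlation). The leukocyte gene PTPRC, seen on 2 of 4 MCF7-RON/MSP arrays and on none of MCF7, was at least 1.4-fold higher (adjusted p = 0.0018), a call that normexp ended, and the B cell gene CD19 rose 2.12-fold (adjusted p = 0.00285). Under quantile normalization the junction, TGF-beta and DNA methylation calls ended (camera adjusted p = 0.133, 0.133 and 0.188), and the marker call was kept at 0.0293 with 6 of 10 risen. The medians of the junction, TGF-beta, DNA methylation and marker lists were -0.11, -0.28, -0.05 and 0.86, and -0.12, -0.27, -0.06 and 0.59 under quantile normalization. Against 10000 random lists matched on signal, a test planned for the markers and extended to the other lists after the data were seen, they lay at percentiles 1.1, 0, 8 and 98.3 (1, 0, 9.2 and 99.3 under quantile normalization).

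No call was made for the other lists. Of mesenchymal genes 8 of 15 rose and 0 fell (camera adjusted p = 0.055, median 0.40, 0.23 under quantile normalization), including the collagen crosslinker LOX (2.13-fold, seen on 1 of 4 MCF7 arrays, a call that normexp ended), the transcription factor TWIST1 (1.98-fold) and the protease inhibitor SERPINE1 (1.75-fold, a call that ended under quantile normalization). The log2 change of TWIST1 was 0.99, but 0.42 under normexp and 0.56 under quantile normalization. Of invasion and metastasis genes 8 of 19 rose and 4 fell (0.753). MMP1 rose by 2.49 (SE 0.12, adjusted p = 3.75e-06, seen on 3 of 4 MCF7 arrays) and CXCR4 rose by 1.5 (adjusted p = 5.64e-07), while the iron-binding secreted protein gene LCN2 fell by 2.05 (adjusted p = 9.05e-05). Of NF-kB and inflammatory genes 7 of 18 rose and 9 fell (0.0799, but 0.0267 under normexp, which called the list down), and adjusted over the list alone 8 rose. The cytokine gene IL32 fell by 2.24 (adjusted p = 7.2e-06), whereas IL6 rose by 1.48 (adjusted p = 0.00136, but 0.55 under normexp). IL1B, seen on 1 of 4 MCF7 arrays, rose by 1.41 (adjusted p = 0.000915), a call that normexp ended. Of estrogen receptor targets 5 of 19 rose and 7 fell (0.055), with SERPINA1 and the progesterone receptor gene PGR down 2.25-fold and 2.22-fold. Luminal identity genes split into 4 risen and 4 fallen of 17 (0.253), among them the secretory genes AGR3, down 7.40-fold, and TFF3, down 1.81-fold.

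Among basal and myoepithelial genes 4 of 17 rose and 2 fell (camera adjusted p = 0.308, median 0.02, -0.10 under quantile normalization), and the integrin gene ITGA6 fell 2.10-fold. MAPK feedback and immediate targets rose in 5 of 21 and fell in 1 (0.733), with the immediate early genes EGR1 and FOSL1 up 2.78-fold and 1.91-fold. Interferon response genes rose in 4 of 24 and fell in 5 (0.284), with IFI44L up 2.58-fold, on 3 of 4 MCF7 arrays above background, and BST2 down 2.05-fold. Antigen presentation genes rose in 4 of 15 and fell in 5 (0.175), and HLA-DRA, not well above background on any MCF7-RON/MSP array, was at least 1.4-fold higher in MCF7. Cell cycle genes rose in 8 of 25 and fell in 6 (0.567), with the mitotic activator CDC20 up 1.32-fold. Counts risen and fallen were 1 and 2 of 8 in mismatch repair (0.302), 8 and 0 of 17 in germline and cancer-testis genes (0.175, median 0.71, but 0.26 with 2 risen under quantile normalization and 0.13 under normexp), 3 and 5 of 20 in hypoxia and glycolysis (0.059), and 2 and 3 of 16 in cholesterol synthesis (0.17), where adjusted over the list alone 1 rose. For p53 targets they were 6 and 1 of 20 (0.308), with the death receptor gene FAS up 2.14-fold, and for the unfolded protein and amino acid response 5 and 3 of 18 (0.903), with the transporter subunit SLC3A2 up 1.68-fold and, adjusted over the list alone, 7 and 4. For fibroblast markers they were 2 and 3 of 6 (0.308), with DCN up 2.58-fold, COL3A1 down 2.14-fold on its brightest probe (-0.23 and -0.42 on the others, neither passing) and, adjusted over the list alone, 3 and 3. Housekeeping genes counted 2 risen and 2 fallen of 14 (0.903), with POLR2A up 1.56-fold. In the remaining lists the counts adjusted over the list alone equalled those over all genes. Under quantile normalization the counts risen and fallen were 4 and 5 for the MAPK list, so their balance turned, 4 and 9 for NF-kB genes, 5 and 4 for invasion and metastasis, 4 and 0 for mesenchymal genes, 2 and 5 for interferon response, 1 and 4 for antigen presentation, 3 and 4 for luminal identity and 1 and 3 for housekeeping genes. Among random lists matched on signal, the uncalled NF-kB list lay at percentile 1.2 (0.9 under quantile normalization, median -0.23) and p53 targets at 98.4 (98.9, median 0.14 under both), and the other uncalled lists lay between 5.7 and 89.3 (6.8 and 90.5). The median was above 0 while camera pointed down in the MAPK, luminal, basal, interferon, cell cycle, mismatch repair and housekeeping lists. Means differed in sign from the medians in luminal identity (-0.21), mismatch repair (-0.04) and fibroblast markers (0.01, median -0.05). With members not above background on any array of a group at their bounds, the medians of the invasion (0.24), NF-kB (-0.09), germline (0.71), unfolded protein (0.09) and blood marker (0.86) lists became 0.05, -0.14, 0.48, 0.07 and 0.80.

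Leaving out 1 array brought lists over the threshold in this comparison. The mesenchymal list passed without MCF7 replicate 4 (camera adjusted p = 0.047), MCF7-RON/MSP replicate 1 (0.0479), or shMBD4 replicate 2 (0.026) or 3 (0.0447), and hypoxia and glycolysis without MCF7 replicate 4 (0.0481), MCF7-RON/MSP replicate 1 (0.0493) or shMBD4 replicate 2 (0.0462). Estrogen receptor targets passed without MCF7 replicate 3 (0.0427) or shMBD4 replicate 2 (0.0462), and NF-kB genes without shMBD4 replicate 3 (0.0447). The mesenchymal list also passed with no filter (0.0129), with only these groups in the fit (0.0316) and with the replicate number as a block (0.0363). The estrogen receptor and hypoxia lists passed with no filter (0.0327 and 0.0378) and with the replicate number as a block (0.0497 for both). Of the 2-fold calls on single genes, 88.9% were rises, but 43.2% were under quantile normalization and 37.4% under normexp, 475 rises and 295 falls passed under both, and 1590 rises were left without MCF7 replicate 1. Each group lay on 1 slide, so slide and group cannot be told apart.

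**Figure D2:**
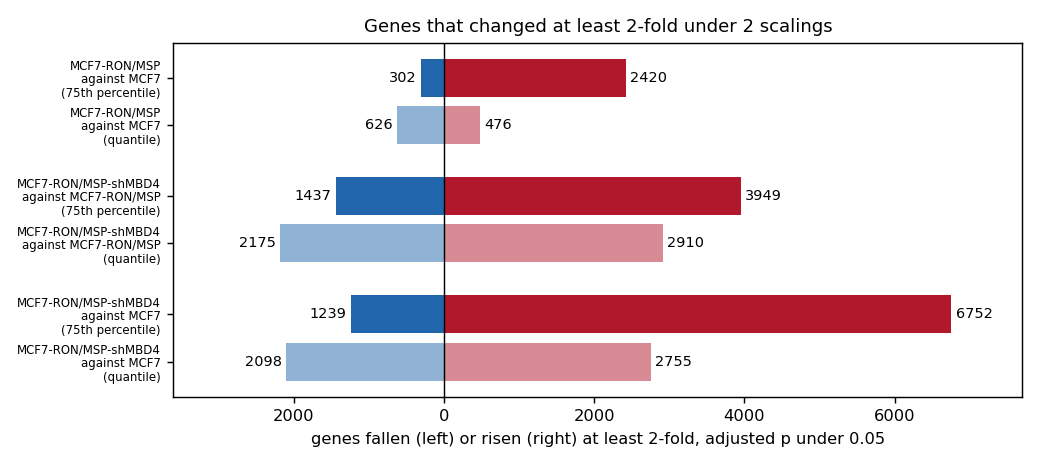
Genes risen (right) or fallen (left) at least 2-fold at an adjusted p under 0.05 in each comparison, with the arrays scaled to the 75th percentile (dark) or quantile normalized (light). Between MCF7-RON/MSP and MCF7 the rises number 2420 under the first scaling and 476 under the second.

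The comparison of MCF7-RON/MSP-shMBD4 with MCF7-RON/MSP asked which transcripts change when MBD4 is depleted in cells that, per the labels, express RON and MSP. MST1R was itself lower in replicates 1 and 2 (-1.13 and -1 against 2.12), so the groups differ in MST1R as well as in MBD4. They also differ in the lentivirus and its hairpin, for which the labels name no control. Of 25 cell cycle genes 20 fell, a call kept under quantile normalization, among them the mitotic genes AURKA (2.24-fold) and CCNB2 (2.59-fold on its brightest probe). Another, dim probe of CCNB2 rose by 1.58, and the mean of its probes read 0.10 and did not pass. The repair genes MLH1 and MSH6 (2.07-fold and 2.04-fold) and HMGCS1 of the sterol pathway (3.05-fold, but log2 -0.50 on its other probe) fell too. The mismatch repair and cholesterol synthesis lists were called down at the preset correlation. With an estimated correlation mismatch repair was not called (adjusted p = 0.0894), and under quantile normalization neither was, with medians of -0.73 and -0.53 against -0.77 and -0.59. The largest rises included the histone genes H4C5 (32.6-fold) and H1-5 (19.6-fold). The epithelial genes KRT8 and CDH1 fell 2.67-fold and 2.60-fold, while AGR3 (4.49-fold) and PATJ (log2 1.73 on its brightest probe) of the same luminal and junction lists rose. Neither list was called, with 7 luminal genes risen and 8 fallen, and 9 junction genes risen and 11 fallen. The matrix gene FN1 fell 4.33-fold and TET2 rose 3.18-fold. In total 9236 genes rose and 7502 fell, of which 3949 and 1437 changed at least 2-fold. The balance of the total turned under quantile normalization (7547 risen, 9515 fallen), normexp (6927 and 11744) and median centring (6982 and 9893). At 2-fold 1641 rose and 1174 fell under normexp. The change also went with signal: the median log2 fold change ran from 0.41 in the dimmest of 5 signal groups to -0.33 in the brightest, where 166 genes rose and 579 fell at 2-fold, and was -0.02 and -0.10 in these groups under quantile normalization. Of the 3949 rises, 662 were of genes not above background on any array of at least 1 of these groups, and 330 of those reached 2-fold at their lower bound.

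Among the 10 largest rises, H4C5 rose by 5.03 (SE 0.14, adjusted p = 8e-09) and H1-5 by 4.29 (SE 0.22, adjusted p = 1.31e-07). Histone genes have similar copies that a probe may read together. The pseudogene CROCCP3, likewise similar to its parent gene, rose by 5 (adjusted p = 3.65e-08), with 1.75 on its other probe, and SLURP1, a secreted epithelial protein gene, by 4.51 (adjusted p = 7.18e-08). ADAMTS7, a matrix metalloprotease gene, rose by 4.14 (adjusted p = 3.1e-08), BCL9, a Wnt coactivator gene, by 3.97 (adjusted p = 4.82e-08), the sperm membrane gene TMEM95 by 3.91 (adjusted p = 2.07e-07), the protease gene KLK11 by 3.87 (adjusted p = 7.81e-08) and S100A5 by 3.85 (adjusted p = 4.7e-08). The incretin receptor gene GIPR rose by 4.06 (adjusted p = 1.97e-07) on its brightest probe, while another probe of it fell by 0.63. ST6GALNAC5, a sialyltransferase gene, SLC18A2, a monoamine transporter gene, and GPRC6A, an amino acid-sensing receptor gene, were not well above background on any MCF7-RON/MSP array. In shMBD4 they were at least 9.43-fold (adjusted p = 7.05e-05), 8.15-fold (adjusted p = 8.13e-06) and 5.71-fold (adjusted p = 1.91e-05) higher by the processed signal (log2 1.11, 0.97 and 0.47 under normexp).

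Among the 10 largest falls, the transcription factor gene NFE2L1, a regulator of proteasome genes, fell by 6.46 (SE 0.09, adjusted p = 4.95e-10) on its brightest probe, whereas its other probes read 0.63, -0.30 and -1.03. ENC1, an actin-binding protein gene, fell by 3.39 (adjusted p = 4.81e-09), while its other probe rose by 2.08. PHF10, of a chromatin remodelling complex, fell by 2.78 (adjusted p = 1.14e-08), with 0.03 on its other probe. The smooth muscle actin gene ACTG2 fell by 4.91 (adjusted p = 4.68e-09) and CYP26A1, which breaks down retinoic acid, fell by 3.19 (adjusted p = 0.000585). The shMBD4 arrays differed among themselves in CYP26A1, with an SD of 1.59. HNRNPA1P27, a pseudogene of a gene with many copies, fell by 2.96 (adjusted p = 3.9e-08), the antimicrobial peptide gene CAMP fell by 2.89 (adjusted p = 1.01e-06) and the zinc transporter gene SLC39A7 fell by 2.85 (adjusted p = 5.03e-06). AOX1, an oxidase gene, fell by 2.68 (adjusted p = 9.12e-08) and PTGS1, a prostaglandin synthase gene, fell by 2.64 (adjusted p = 4.43e-05).

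The cell cycle list moved down with 20 of 25 members fallen and 1 risen (camera adjusted p = 1.23e-05, adjusted p = 0.0404 with an estimated correlation). AURKA, a mitotic kinase gene, fell by 1.17, as did the cyclin genes CCNE2 (log2 -1.14) and CCNB1 (log2 -1.08). CCNB2 fell by 1.38, but another, dim probe rose by 1.58, and the mean of its probes read 0.10 and did not pass. DNA methylation and base excision repair moved down with 17 of 28 fallen and 4 risen (0.00451, adjusted p = 0.0474 with an estimated correlation). The glycosylase gene NTHL1 fell by 1 and the methyl-CpG binding protein gene MECP2 fell by 1.22 on its brightest probe, with 0.23 on the other, while TET2 rose by 1.67. In mismatch repair 7 of 8 fell and 1 rose (0.0117, adjusted p = 0.0894 with an estimated correlation), including MLH1 (log2 -1.05), MSH6 (log2 -1.03) and MSH2 (log2 -1). Cholesterol synthesis fell in 12 of 16 and rose in 1 (0.00014, adjusted p = 0.0347 with an estimated correlation), including the synthase gene HMGCS1 (log2 -1.61, -0.50 on its other probe), the isomerase gene IDI1 (log2 -1.40), the sterol carrier gene STARD4 (log2 -1.13) and the epoxidase gene SQLE (log2 -1.1). Housekeeping genes fell in 10 of 14 and rose in 1 (0.0111, adjusted p = 0.0894 with an estimated correlation), with SDHA down 1.84-fold and POLR2A up 1.85-fold (log2 0.89, 0.39 on its other probe, which did not pass). The medians of these lists were -0.59, -0.42, -0.77, -0.59 and -0.42 in that order, and -0.36, -0.33, -0.73, -0.53 and -0.08 under quantile normalization. Random lists matched on signal had medians of -0.28, -0.16, -0.19, -0.26 and -0.31. Among them the lists lay at percentiles 1.1, 3.3, 0.8, 2.9 and 26.2 (3.4, 4.8, 0.5, 0.7 and 59.1 under quantile normalization). The fall of the housekeeping genes was thus within that of equally bright genes. DNA methylation also lay within the middle range of matched lists (-0.44 to 0.14, and -0.37 to 0.2 under quantile normalization). So did cholesterol synthesis with the main values (-0.6 to 0.12) and cell cycle under quantile normalization (-0.38 to 0.19). Only mismatch repair lay below its range under both scalings. Fibroblast markers rose in 4 of 6 (0.0277, adjusted p = 0.257 with an estimated correlation, 0.0637 without shMBD4 replicate 3, percentile 97.2 of matched lists, 99.2 under quantile normalization), with the collagen genes COL3A1 and COL1A1 up 3.75-fold and 3.22-fold and THY1 up 2.26-fold. Under quantile normalization the cell cycle call was kept (0.0202), and the calls for DNA methylation (0.109), mismatch repair (0.0643), cholesterol synthesis (0.0593), fibroblast markers (0.0643) and housekeeping genes (0.72) ended. Normexp ended the calls for DNA methylation (0.143), mismatch repair (0.143), fibroblast markers (0.0843) and housekeeping genes (0.161), with medians of -0.40, -0.76, 0.92 and -0.40. The fibroblast median was 1.09 with the main values and 1.05 under quantile normalization. The mean of probes ended DNA methylation (0.266, median -0.09) and fibroblast markers (0.0502, median 1.18), which also ended with no filter (0.228, median 0.43).

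The other lists were not called. Interferon response genes fell in 13 of 24 and rose in 4 (camera adjusted p = 0.137, but 0.004 without shMBD4 replicate 3), with a median of -0.59 (-0.63 under quantile normalization) at percentile 0 (0.1) of matched lists. IFIT2, an interferon-induced gene, fell by 2.09 (adjusted p = 0.0101), although the mean of its probes did not pass. Epithelial junctions rose in 9 of 24 and fell in 11 (0.637, median 0.00, 0.06 under quantile normalization, -0.20 under median centring), with PATJ up 3.32-fold on its brightest probe (log2 1.73, 0.28 to 1.32 on the others), the desmosome gene DSC2 up 2.66-fold and CDH1, which encodes E-cadherin, down 2.60-fold. Mesenchymal genes rose in 5 of 15 and fell in 6 (0.551, median -0.14), but in 3 and 8 under quantile normalization (median -0.61, -0.49 under normexp), at percentile 5 (1.5 under quantile normalization) of matched lists, with FN1 and TGFBI, matrix protein genes, at log2 -2.11 (adjusted p = 1.1e-06) and -1.68 (adjusted p = 9.54e-08). The other FN1 probes read -2.29 and, on a dim one that did not pass, -0.21. TGF-beta targets rose in 10 of 18 and fell in 5 (0.551). ID2 rose 7.5-fold on its brightest probe (log2 2.91, 1.54 on its other, almost equally bright probe). The activin subunit INHBA fell 3.04-fold (log2 -1.6, -0.98 on its other probe). Luminal identity genes rose in 7 of 17 and fell in 8 (0.551, median 0.07, -0.13 under median centring), with AGR3 up 4.49-fold and the luminal keratin KRT8 down 2.67-fold. Estrogen receptor targets rose in 6 of 19 and fell in 10 (0.556, median -0.15, 0.19 under quantile normalization), with the scaffold PDZK1 down 3.52-fold and the protease CTSD and SERPINA1 up 2.80-fold and 2.59-fold. Basal and myoepithelial genes rose in 5 of 17 and fell in 5 (0.755, median 0.06, -0.01 under normexp, -0.19 under quantile normalization, -0.14 under median centring), with the keratin KRT17 down 3.07-fold.

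Among invasion and metastasis genes 6 of 19 rose and 6 fell (camera adjusted p = 0.904, median 0.22, -0.15 under normexp, -0.07 under quantile normalization), with the matrix signalling gene CCN2 up 2.59-fold, a call that normexp ended, and MMP1 down 2.45-fold. NF-kB and inflammatory genes rose in 5 of 18 and fell in 6 (0.551), with the chemokine CXCL3 up 4.92-fold and LTB down 4.61-fold. Antigen presentation genes rose in 7 of 15 and fell in 3 (0.551). HLA-DRA was at least 2.31-fold higher than in MCF7-RON/MSP, where no array was well above background, a call that normexp ended, and HLA-DMA rose 2.75-fold (log2 1.46, 0.53 on its other probe). MAPK feedback and immediate targets rose in 7 of 21 and fell in 4 (0.755, median 0.22, -0.07 under quantile normalization), with the feedback inhibitor SPRY1 up 2.96-fold and FOSL1 up 2.93-fold. Germline and cancer-testis genes rose in 4 of 17 and fell in 2 (0.86, median 0.00, -0.37 under quantile normalization), and adjusted over the list alone 3 rose. MAGEA1 fell by 2.56, with 1 of 3 shMBD4 arrays above background, and MAGEA6 rose by 1.88. Counts risen and fallen were 4 and 10 of 20 in p53 targets (0.187) and 7 and 6 of 18 in the unfolded protein and amino acid response (0.84, median 0.07, -0.07 under normexp, -0.13 under median centring). In hypoxia and glycolysis they were 5 and 9 of 20 (0.551), or 6 and 9 adjusted over the list alone, with VEGFA up 2.93-fold on its brightest probe but with -0.17 and -0.55 on a pair of its other probes. Blood and immune cell markers rose in 3 of 10 and fell in 0 (0.551, median 0.26, -0.08 under normexp, -0.21 under quantile normalization), with the B cell receptor gene CD79A up 4.32-fold. The counts adjusted over the list alone equalled those over all genes in the other lists. Under quantile normalization the counts risen and fallen were 3 and 16 for interferon response, 9 and 7 for each of the junction, luminal and estrogen receptor lists, whose balance turned, 4 and 8 for invasion and metastasis, 2 and 8 for NF-kB genes, 5 and 5 for the MAPK list, 5 and 6 for basal genes, and 2 and 5 for germline genes and 1 and 3 for blood and immune cell markers, whose balance turned too. Of the other uncalled lists, NF-kB genes lay at percentile 2.2 of matched lists (20.9 under quantile normalization) and luminal identity at 96.8 (98.7), and the rest lay between 5.4 and 92.2 (10 and 95.7). The median and the direction of camera differed in sign for the luminal, basal, invasion and unfolded protein lists, and so did the mean (0.06) and camera for epithelial junctions. Means differed in sign from medians in the luminal (-0.04) and basal (-0.07) lists. With members not above background on any array of a group at their bounds, the medians of the basal and invasion lists were 0.00 and 0.04. The share of rises among 2-fold calls was 73.3%, against 57.2% under quantile normalization (2910 risen, 2175 fallen) and 54.8% under median centring (3036 risen, 2505 fallen), and 2753 rises and 1123 falls passed under both the 75th percentile and quantile scaling. All shMBD4 arrays were scanned on a later day than the rest, so scan day and knockdown cannot be told apart.

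**Figure D3:**
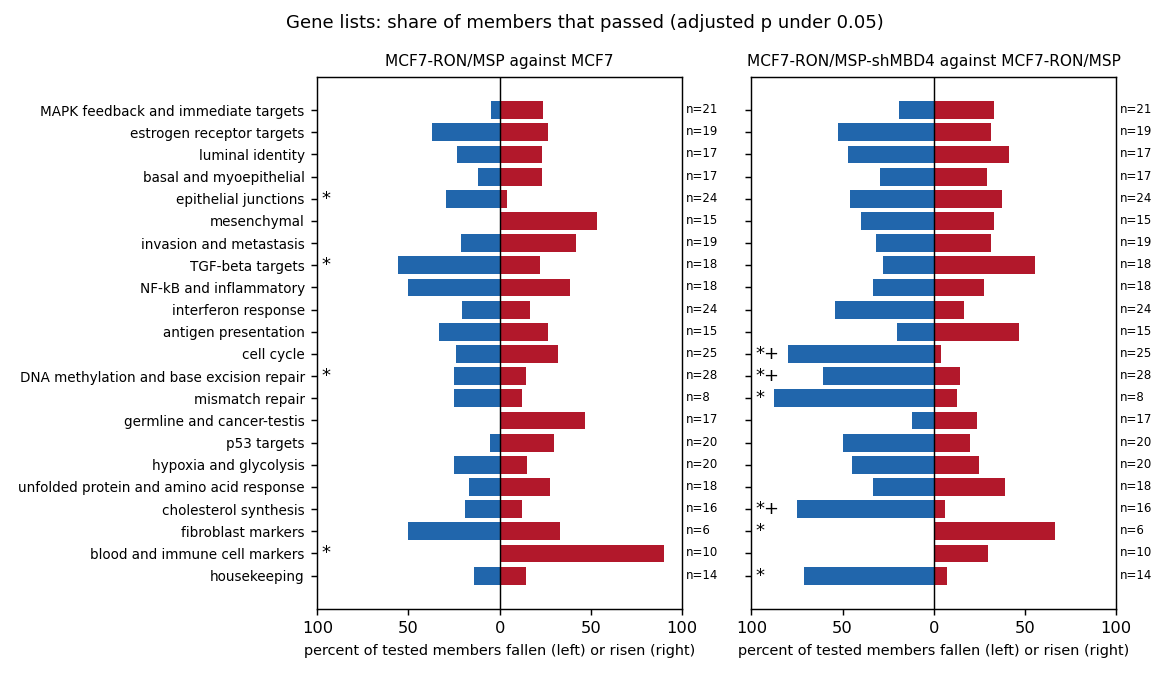
Percent of each list's tested members (n) that fell (left) or rose (right) at an adjusted p under 0.05 in MCF7-RON/MSP against MCF7 and in shMBD4 against MCF7-RON/MSP. A star marks lists that camera called at the preset correlation and a plus those also called at an estimated one, which in the second comparison were cell cycle, DNA methylation and base excision repair, and cholesterol synthesis.

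Against MCF7, the shMBD4 cells differed in 12789 risen and 7125 fallen genes, of which 6752 and 1239 changed at least 2-fold. The balance of the total turned under quantile normalization (7678 risen, 8568 fallen) and normexp (7775 and 10124). At 2-fold 1823 rose and 1043 fell under normexp. Of the 6752 rises, 1190 were of genes not above background on any array of at least 1 of these groups, and 452 of those reached 2-fold at their lower bound. The largest rises were in CROCCP3 (56.1-fold on its brightest probe), H4C5 (43.8-fold), GIPR (36.4-fold on its brightest probe), S100A5 (30.2-fold) and TMEM95 (27.9-fold). Another probe of CROCCP3 changed by -0.98 with RON/MSP and by 1.75 with shMBD4, and another of GIPR by 1.19 and -0.63. The largest falls were in NFE2L1 on its brightest probe (90.9-fold), ACTG2 (41.7-fold), LTB (37.3-fold), ASCL1 (28.9-fold) and S100A8 (27.0-fold). LTB fell at both steps, at log2 -3.02 with RON/MSP and -2.21 with shMBD4 (adjusted p = 6.94e-05).

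The lists called here included cell cycle, with 18 of 25 fallen (camera adjusted p = 4.61e-06, adjusted p = 0.0219 with an estimated correlation), DNA methylation and base excision repair, with 18 of 28 fallen (0.000278, adjusted p = 0.0219 with an estimated correlation), and cholesterol synthesis, with 13 of 16 fallen (5.73e-06, adjusted p = 0.0145 with an estimated correlation). Mismatch repair fell in 7 of 8 (0.0033, adjusted p = 0.0601 with an estimated correlation) and housekeeping genes in 9 of 14 (0.0065, adjusted p = 0.0644 with an estimated correlation). Interferon response genes fell in 12 of 24 (0.0186, adjusted p = 0.589 with an estimated correlation, 0.054 without shMBD4 replicate 2). Blood and immune cell markers rose in 9 of 10, or in 10 adjusted over the list alone (0.0282, adjusted p = 0.375 with an estimated correlation, 0.0545 with the mean of probes), with a median of 1.23, or 1.05 with members at their bounds, 0.31 under quantile normalization (5 risen, 1 fallen) and 0.38 under normexp. Among random lists matched on signal, these medians lay at percentiles 3.1, 1.6, 0.1, 1.8, 19.3, 0 and 90 in that order (7.9, 0.2, 0.2, 1, 31.2, 0 and 77.6 under quantile normalization). The uncalled NF-kB list lay at percentile 0 (0.3) and the basal list at 2.1 (18.4). Without shMBD4 replicate 1 luminal identity (0.0366) and without replicate 3 NF-kB genes (0.0435) also passed. Under quantile normalization the calls for housekeeping genes (0.786, median -0.20) and blood and immune cell markers (0.203) ended. Normexp ended those for interferon response (0.114, median -0.50), blood and immune cell markers (0.176) and housekeeping genes (0.147, median -0.45), and the strict filter that for interferon response (0.0599). Median centring added epithelial junctions (0.0486), and, each at 0.0457, estrogen receptor targets, fibroblast markers, hypoxia and glycolysis, and luminal identity. Rises were 84.5% of 2-fold calls, 56.8% under quantile normalization (2755 risen, 2098 fallen) and 70% under median centring, and 2619 rises and 994 falls passed under both the 75th percentile and quantile scaling.

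Genes that moved one way with RON/MSP and the other way with shMBD4 were compared next, since the series asks whether RON acts through MBD4. Of the 302 genes that fell at least 2-fold with RON/MSP, 151 rose at least 2-fold with shMBD4, where independent lists of these sizes would share 46. Of the 2420 that rose, 96 fell, where independent lists would share 134. Under quantile normalization the counts were 294 against 70.3 and 134 against 39.9, and under normexp they dropped to 39 against 7.2 and 28 against 3.1. The second count thus lay below the independent value with the main values and above it in these alternatives. Genes that rose at both steps numbered 166, more than the 96 that moved back, against 369 for independent lists. Those that fell at both numbered 14 against 16.7. Under quantile normalization these counts were 16 against 53.4 and 30 against 52.5. Besides MST1R, genes that rose and then fell included HOXB2 (2.11, then -2.30, or 2.30, then -1.01 on its other probe), KRT16P3, a keratin pseudogene with near-identical copies (1.86, then -1.97), and the transcriptional cofactor ZFPM2 (3.08, then -1.85, seen on 1 of 4 MCF7 arrays, its rise 0.67 under normexp). Genes that fell and then rose included the phosphodiesterase PDE8B (-2.54, then 2.76, but -1.1, then 1.05 under normexp), KLK12 (lower by at least 3.39, then higher by at least 2.35, but -1.35, then 0.49 under normexp), SEMA3D (-3.92, then 2.39), SPANXD (-4.40, then 2.25) and AGR3 (-2.89, then 2.17). SEMA3D had an SD of 1.78 over the 3 shMBD4 arrays, so the size of its rise is imprecise.

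These comparisons share the 4 MCF7-RON/MSP arrays, which by itself gives fold changes of opposite sign. Unchanged groups simulated 100 times gave a correlation of -0.463 across genes, which are not independent replicates, a covariance of -0.020 and no more than 0 genes at 2-fold in opposite directions. The simulated groups held no true change. That 0 therefore does not show how many opposite moves sharing gives among genes that truly change. The observed correlation was -0.147 and the covariance -0.078, a difference in covariance of -0.058 (-0.138 under quantile normalization). With the MCF7-RON/MSP arrays split so that none was shared, the correlation ran from -0.155 to -0.079, 106 to 120 genes fell and then rose, and 67 to 83 rose and then fell. All 4 of these arrays lay on 1 slide, so an error common to that slide would stay in both parts of a split. The simulation held no such error either. Opposite moves that come from the slide are therefore not excluded. Among the 194 named genes that fell with RON/MSP, the median shMBD4 array value relative to MCF7-RON/MSP was 1.05, 1.04 and 0.30 for replicates 1, 2 and 3. MST1R read -1.13, -1 and 1.40 in the same replicates, so these genes moved back least in the replicate with the most MST1R. Replicate 3 also had the highest MBD4 (-0.63 against -0.92 and -0.89), and over all probes it lay nearer to MCF7-RON/MSP, with correlations of 0.972 to 0.973 against 0.958 to 0.964 for replicates 1 and 2, so the smaller move was not particular to these genes. With MCF7 the correlations were 0.963 to 0.968 for replicates 1 and 2 and 0.9685 to 0.9723 for replicate 3. Replicates 1 and 2 each correlated more with MCF7 than with MCF7-RON/MSP. The SDs of the differences did not show that order, at 1.044 to 1.21 with MCF7 and 1.017 to 1.109 with MCF7-RON/MSP. A relation of the moves to MST1R was not tested, since 3 arrays would allow only a very weak test, and lower MST1R and lower MBD4 cannot be told apart here. Among the 1181 that rose the median was -0.25, 0.01 and 0.01. Under quantile normalization these medians were 0.61, 0.56 and 0.09 among 295 fallen genes and -0.97, -0.75 and -0.47 among 249 risen ones.

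**Figure D4:**
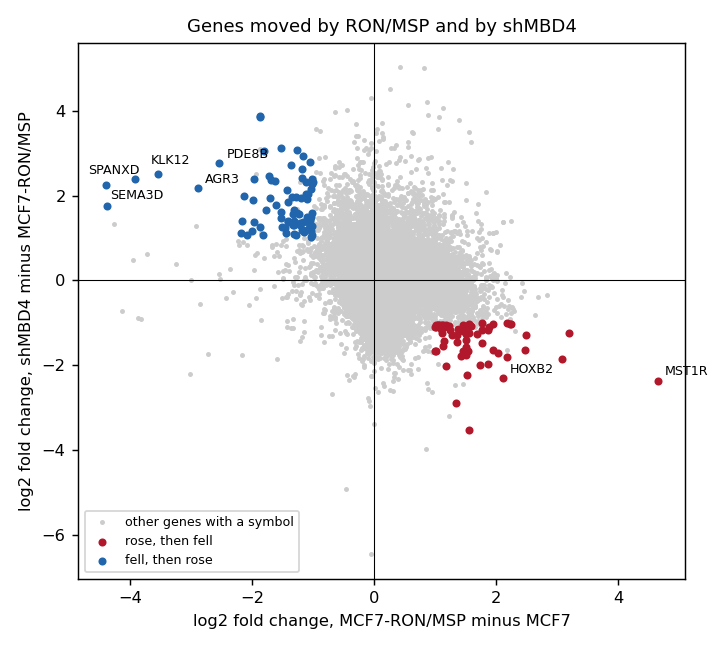
Log2 fold change with RON/MSP (MCF7-RON/MSP minus MCF7, horizontal) against that with shMBD4 (shMBD4 minus MCF7-RON/MSP, vertical) for each gene with a symbol. Coloured points changed at least 2-fold at an adjusted p under 0.05 in both, in opposite directions; MST1R lies at 4.65 and -2.36.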

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

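Of the tests here, those on spike-in signals of dim probes, on MBD4 as a check of labels and on MST1R within a slide were chosen after the result was seen. Among 248 groups of 4 arrays tested for named genes, 11 held an array whose gap to the rest, over the group's range, passed the critical value of Dixon's test, and chance gives about 1 in 20.

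OLFML1 read -0.84 in MCF7-RON/MSP replicate 2, against -4.11 to -3.86 in the others. ASCL1 read 0.55 in MCF7 replicate 2, against 0.48 to 0.49. CFB read -1.36 in MCF7 replicate 4, against -1.60 to -1.56. PGR read 0.76 in MCF7 replicate 3, against 0.96 to 0.98. TFF3 read 6.15 in MCF7 replicate 3, against 6.23 to 6.25, and 5.53 in MCF7-RON/MSP replicate 1, against 5.29 to 5.31. ITGA6 read -0.66 in MCF7-RON/MSP replicate 4, against -0.57 to -0.55. ID2 read 0.23 in MCF7-RON/MSP replicate 1, against 0.09 to 0.11. BST2 read -1.17 in MCF7-RON/MSP replicate 2, against -1.05 to -1.04. CTSD read 2.67 in MCF7-RON/MSP replicate 1, against 2.73 to 2.74. IDI1 read 3.63 in MCF7-RON/MSP replicate 4, against 3.68 to 3.69. The bright external spike-in RNAs, which enter no comparison, lay 0.63 higher relative to the 75th percentile in the shMBD4 arrays than in MCF7-RON/MSP (3.08 to 3.88 per array, against 2.40 to 2.87 in the other 8 arrays).

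Most 2-fold calls between MCF7-RON/MSP and MCF7 were rises of dim genes: the median log2 fold change was 0.72 and 0.44 in the 2 dimmest of 5 signal groups and 0.05, 0.02 and 0.01 in the brighter ones. The pattern depends on the scaling: under quantile normalization the 2 dimmest groups had medians of 0.17 and 0.10, and 476 genes rose and 626 fell at 2-fold. Blood or immune cells in the MCF7-RON/MSP cultures may contribute, since the median of their markers lay at the 98.3 percentile of 10000 random lists matched on signal. MCF7 also expressed 7 of the 10 markers, and against a large share PTPRC (-7.08) and the abundant globin transcript HBB (-7.04, looked up after its values were seen) stayed dim, and HLA-DRA was not above background on any MCF7-RON/MSP array. A signal trend of the slide could also raise any dim probe, but the dim spike-in RNAs differed from the brighter ones by a median of 0.12 with values far apart, and slide and group cannot be told apart. An effect of RON/MSP itself stays open and was not tested.

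The shMBD4 arrays stood apart from the other 8, with 5386 genes at 2-fold against MCF7-RON/MSP and 7991 against MCF7. A labelling and scan batch is a candidate explanation: probes of 1 gene disagreed more between shMBD4 and MCF7-RON/MSP than between MCF7-RON/MSP and MCF7, with an SD 2.82 times as large. Larger changes of any cause can raise that SD as well, so the ratio alone does not point to a batch. The correlation between a pair of probes of 1 gene, which does not depend on that size, was 0.365 against 0.563. Probe-specific change, as from splicing, would also raise the ratio and lower the correlation, and it was not tested. Loss of MBD4 cannot be told apart from the batch, because 0 arrays without the knockdown were scanned on the later day.

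MST1R was lower in 2 of the 3 shMBD4 arrays (-1.13 and -1) than in replicate 3 (1.40), although all came from the RON/MSP line per the labels. Cells without the knockdown in those arrays are argued against, since the highest MBD4 of any shMBD4 array lay below the lowest of the other 8 by a difference of -2.12. That argument rests on the 1 probe for MBD4, whose fall cannot be told apart from the scan day. For the MST1R difference a scan batch is argued against as well, since replicates 2 and 3 shared a slide and scan day and differed by 2.4. Loss of the introduced receptor in culture and differences between cultures stay open as untested explanations.

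For the number of genes at 2-fold in each comparison, a chance assignment of arrays to groups is argued against. Other splits of the same arrays into groups of these sizes gave fewer, among 35 splits with the real one included. Each group lay on its own slides, and shMBD4 was also scanned on another day, so the real split is the one that follows slide and day. A batch effect is therefore not excluded. For MCF7-RON/MSP against MCF7 there were 2722 genes and at most 2 in another split, for shMBD4 against MCF7-RON/MSP 5386 and at most 2569, and for shMBD4 against MCF7 7991 and at most 5145. For the 247 genes that moved in opposite directions, at most 13 were found in another of 100 splits drawn, the real one included. A split that mixes the groups can also leave fewer changed genes in either comparison. It therefore does not test whether the gene lists overlap more than independent ones would. On that measure 151 genes fell then rose against 46 for independent lists, while 96 rose then fell against 134.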

How the results depend on the processing

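Counting genes that passed under both scalings was chosen after the data were seen. The MBD4 decrease kept its direction and passed under every alternative run, from -2.69 to -2.42. It rests on 1 probe, and no alternative could separate the knockdown from the later scan day. Of 164 named gene results, 160 kept their call in every run that left out 1 array.

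Normexp background gave 68 risen and 114 fallen genes at 2-fold for MCF7-RON/MSP against MCF7, 1641 risen for shMBD4 against MCF7-RON/MSP and 1823 risen for shMBD4 against MCF7, with 2 and 4 lists called in the latter comparisons, 28 and 39 opposite moves (rose then fell, and fell then rose) and a correlation of -0.217. Of 163 passing named gene results, 31 changed under normexp by less than 50% of their main value, among them MMP1 (0.87), ZFPM2 (0.67), TWIST1 (0.42), IL6 (0.55), IFI44L (0.35), DCN (0.46), CD19 (0.41), HOXB3 (0.92), GAGE12F (1.01) and CES1 (0.97) with RON/MSP, MAGEA1 (-0.91) and COL3A1 (0.89) in shMBD4, PDE8B in both (-1.1 and 1.05), and the genes given as bounds. It ended the calls of ADGRD1, LOX (0.13), IL1B (0.21) and PTPRC in MCF7-RON/MSP and of CCN2 (0.64) and HLA-DRA (0.06) in shMBD4. Quantile normalization gave 476 risen and 626 fallen, 2175 fallen, and 2755 risen and 2098 fallen in the same order of comparisons, 1 list called in each of the first pair, 294 genes that fell then rose and a correlation of -0.341. It ended ADGRD1 and SERPINE1 (0.37, adjusted p = 0.0783). Median centring gave 2505 fallen for shMBD4 against MCF7-RON/MSP, 2184 fallen and 12 lists for shMBD4 against MCF7, and 166 genes that rose then fell. Passing under both scalings left 475 rises with RON/MSP and 2619 in shMBD4 against MCF7. The strict filter, which tests fewer genes, left 914, 2608 and 3831 rises, 1 list with RON/MSP, and 52 and 91 opposite moves. With no filter 7 lists were called with RON/MSP, and with no fold threshold 2312 genes rose then fell and 1792 fell then rose. An estimated correlation left 0, 3 and 3 lists in the order of comparisons, and fry, which compares with no other genes, gave 11, 14 and 22. Apart from the strict filter, the fold threshold and the kind of list test, the cause was not tested.

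The direction turned for CCNB2 in shMBD4 with the mean of probes (0.10), which brings in a dim probe that rose. Among the lists fry called, it pointed up where camera pointed down for housekeeping genes with RON/MSP (median 0.06) and, in shMBD4 against MCF7, for mesenchymal genes (0.49), TGF-beta targets (0.04), antigen presentation (0.21) and the unfolded protein response (0.06), whose medians relative to all genes were -0.06, 0.16, -0.3, -0.13 and -0.27 in that order. The mean of probes also ended the IFIT2 call (-0.80). Splits of the MCF7-RON/MSP arrays gave correlations of -0.079 and -0.081 at the smallest in size.

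Leaving out 1 array gave 1590 to 2944 rises and 265 to 325 falls with RON/MSP, 3668 to 4384 and 1324 to 1766 for shMBD4 against MCF7-RON/MSP, and 6074 to 7125 and 1203 to 1407 for shMBD4 against MCF7. Lists called ran from 3 to 7, from 6 to 6 and from 6 to 8, opposite moves from 77 to 133 and from 128 to 206, the correlation from -0.182 to -0.11, and MBD4 from -2.58 to -2.44.

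Replicate numbers did not pair the arrays: arrays of the same number deviated from their group means with correlations of -0.11 to 0.2, 1 of 10 over 0.1. With the replicate block 2396 genes rose and 295 fell at 2-fold with RON/MSP, 3967 and 1432 for shMBD4 against MCF7-RON/MSP and 6911 and 1239 against MCF7, with 84 and 151 opposite moves, and 7 lists were called with RON/MSP. The block ended the MST1 call in shMBD4 (adjusted p = 0.0918). The slide as a random block (consensus correlation 0.14) ended OLFML1 (0.0765), TGFB2 (0.0727) and COL1A1 (0.0603) with RON/MSP and MST1 in shMBD4 (0.0801). MBD4 passed with RON/MSP when only those groups entered the fit (adjusted p = 0.0112). The series table, the outlier spots and the intensity trend changed no call on a named gene. Signal over background limits what can be said of the dim genes.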

Other observations

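The tests in this part, on HOX genes, histone genes and S phase genes, were all chosen after their values were seen.

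HOXB2 and HOXB3, among the largest rises in MCF7-RON/MSP, drew attention to their cluster of developmental transcription factors, whose neighbouring genes may move together. Of the 7 other HOXB genes tested, 6 rose, such as HOXB6 by 1.22 and HOXB7 by 0.95, while HOXB9, the brightest, read -0.25 and did not pass. Their median, with HOXB1 at its bound because it was above background on no MCF7 array, was 0.76, at percentile 96.7 of 10000 random lists matched on signal. Under quantile normalization it was 0.37, at percentile 93.3, with 4 of 7 risen. A move of the whole cluster thus stays open, since these genes lay high among equally dim ones but within the range of matched lists (-0.11 to 0.79). Of the separate HOX clusters, HOXA lay at percentile 95.7 (98.3 under quantile normalization, though there 1 of 8 rose), HOXC at 20.4 (11.7) and HOXD at 81.4 (67.9), so the high placing was shared by HOXA but not by HOXC. In shMBD4 HOXB2 fell by 2.30 and HOXB7 rose by 2.29.

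Replication-dependent histone genes were higher in shMBD4 than in MCF7-RON/MSP: 54 of 63 rose and 3 fell, 31 rose at least 2-fold, and the median was 0.98 (1.05 under quantile normalization). With the 3 of them that were not above background on any array of a group at their bounds, 29 rose at least 2-fold and the median was 0.84 (0.97). Histone genes with polyadenylated transcripts differed, with 0 of 9 risen, 4 fallen and a median of -0.23 (0.03 under quantile normalization, where 1 rose and 2 fell). The first group lay at percentile 100 of matched lists and the second at 72.1. Since these histone transcripts lack a poly(A) tail, a difference in which RNAs were labelled may account for this, and it cannot be separated from the knockdown because all shMBD4 arrays were scanned on another day. More cells in S phase are argued against, as far as these would raise S phase genes as much as the histone genes: 7 of 8 S phase genes fell, with a median of -0.59 (-0.37 under quantile normalization). That median lay at percentile 11 (12.9) of matched lists, whose own median was -0.31, so the fall itself was within that of equally bright genes. The same histone genes already lay higher in MCF7-RON/MSP than in MCF7, where 40 of 63 rose and 2 fell with a median of 0.37 (0.33 under quantile normalization).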
